A study of Homo sapiens with 4 samples.

How the data were processed

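RNA was measured in 4 libraries of CD4 T cells sorted from 2 digested human cutaneous melanoma lesions. Per the labels, live single CD45+ CD3+ CD4+ CD8- cells were sorted further on CD25 and CD27, RNA was taken with silica spin columns, cDNA was made with a kit for very small RNA amounts (SMARTer), and 50 bp paired-end reads without strand information were sequenced. The deposited values are raw counts of reads per Ensembl gene, not normalized. TopHat2 2.0.12, SAMtools and HTSeq 0.6.1p1 and the builds hg19 and GRCh37 are named, per the submitters' processing notes. The annotation release and the strand setting of the counting are not given in the sources used here. Without strand, reads of a gene and of an antisense partner cannot be told apart, and reads of near-identical genes such as HSPA1A and HSPA1B may be split or lost.

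The table held 63677 gene rows and 5 summary rows of the counter, 2 of which held 0. Summary rows were kept out of library sizes and tests. Reads in no gene made up 14.1%, 11.1%, 12.2% and 21.5% of the reads listed for Treg replicate 1, Treg replicate 2, Teff replicate 1 and Teff replicate 2. Ambiguous reads made up 5.06%, 5.31%, 5.18% and 3.09%, and reads aligned to several places 23.6%, 21.5%, 22.5% and 31.6%. Reads assigned to genes numbered 23650483, 18638373, 20568117 and 22149040 and fell on 23485, 20127, 24345 and 23631 genes. The 10 genes with the most reads took 9.39%, 8.23%, 9.56% and 15.8% of them, and mitochondrially encoded genes 1.77%, 2.19%, 3.15% and 3.72%. A count of 0 was read as allowing up to 3 reads. Symbols were matched by Ensembl identifier for 52181 gene rows (81.9%); the reference annotation was of another build (GRCh38), so it was used only for names, gene types and chromosome class, and no coordinates are given. Identifiers with no symbol held 1.20% to 1.44% of the assigned reads. Of 347 symbols in the gene lists, CCL3 and CCL4 matched no row and 22 others were listed at 0 in all libraries, among them CCL5, PECAM1 and IL17A. Such a row may not be the one that the authors' annotation filled, so these genes are not analysed here.

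Groups and replicate numbers were taken from the titles. Genes were kept by edgeR's filterByExpr (17481 genes), libraries were scaled by TMM (factors 1.15, 1.02, 1.07 and 0.80 in the order above), and Treg was compared with Teff by edgeR's quasi-likelihood test (edgeR 4.0.16, glmQLFit with legacy set to FALSE, no covariate) with Benjamini-Hochberg adjustment at 0.05. The SE of a log2 fold is the fold divided by the square root of its F statistic. CPM values are TMM-scaled and have no prior count; log2 ratios within a tumour use log2 CPM with a prior count of 2. The test, the design, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined. With 2 libraries per group an exact permutation test cannot reach 0.05, and marker sums and read shares are given as values without a test.

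The genes named are FOXP3, IL2RA, CD27, IKZF2 and CTLA4 as a check of the labels; the 12 genes with the largest fold in each direction among those that passed with at least 10 CPM in the higher group and the same direction in both tumours, or, where fewer than 5 passed as here, the 8 with the smallest p in that direction; and up to 4 genes with the smallest p of each list. The text gives examples from that last part, and other list members (FOS, DUSP1, IER2, HSPB1, MKI67, CD3D, CD28, KIT and TYRP1) were chosen after their values were seen. Sex-linked marker genes, immunoglobulin and T cell receptor segments, HLA-DRB genes and genes whose copy number differs between people were not named, and a few single genes are not reported here.

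Gene lists numbered 33, of which 22 hold T cell programmes and 11 hold markers of other cell types; 28 with at least 3 tested genes were tested. The test was camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 28 lists. Camera with an estimated correlation and fry (directional and mixed) were run beside it; fry does not compare a list with other genes. Some lists share genes. In 3 lists a gene was at 0 in both Treg libraries, and setting it to 3 reads per library moved 0 of their medians.

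Replicate numbers pair the libraries by tumour, per the labels. The correlation over genes of same-numbered libraries' deviations from their group means was -0.03. In a check on donor-linked genes, the 2 libraries of 1 of the 2 tumours did not match each other, as 1 library stood alone. With 1 library alone, no other pairing of the 4 libraries would match in both tumours. The labelled lesion of a library may therefore be in doubt, and the pairing is uncertain for 1 tumour. Blocked values and ratios within a tumour carry that limit.

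Alternatives were a replicate block, DESeq2 size factors, library size only, upper quartile scaling, DESeq2's Wald test (DESeq2 1.42.0) with and without the block, limma-voom, no filter, a filter of 10 CPM in at least 2 libraries, leaving out mitochondrial, ribosomal protein and receptor segment genes, a threshold of 0.10, edgeR's legacy fit, each tumour alone (ratios, no test), each library left out in turn, and for lists a prior count of 0.5. They were applied to the counts of genes, the lists, and the label check and smallest-p genes. The procedure was tested on simulated data: 17481 genes with the means and library sizes of these libraries, of which 60 were changed 2-fold, 70 changed 4-fold and 70 changed 16-fold. With the dispersion trend of the libraries it called 0%, 0% and 24.3% of these, in that order, and 0 unchanged genes, and a list shifted on purpose had an adjusted p of 0.101. With a dispersion 10 times smaller it called 18.3%, 72.9% and 100% and 12 unchanged genes, and the shifted list had an adjusted p of 3.96e-24. After the data were seen, 10 further melanocyte genes outside the lists were chosen, before their own values were seen, for a test in the closing section. Exact 95% binomial (Clopper-Pearson) intervals cover counting error only. R 4.3.3 and Python 3.11.15 with pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.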

Results

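RNA was sequenced from CD4 T cells sorted out of 2 human cutaneous melanoma lesions after collagenase digestion. Per the labels, each lesion gave 1 library titled Treg (regulatory T cells, which restrain immune responses) and 1 titled Teff (effector T cells). The 4 libraries thus formed 2 groups of 2. Replicate 1 of each group came from tumour 1 and replicate 2 from tumour 2, per the labels. A check on donor-linked genes left this pairing uncertain for 1 of the 2 tumours, and ratios within a tumour carry that limit. Values were whole-read counts per gene, given here as CPM, the reads of a gene divided by the scaled read total of its library. Reads assigned to genes came to 23650483 in Treg replicate 1, 18638373 in Treg replicate 2, 20568117 in Teff replicate 1 and 22149040 in Teff replicate 2. At these depths a count of 0 allows up to 3 reads, or 0.111 to 0.170 CPM, a limit that covers counting error only because amplified reads are not independent molecules. P-values of single genes measure only the spread between these samples. Those of camera for gene lists rest mainly on the spread across genes, taken as nearly independent (preset correlation of 0.01).

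The first comparison asked whether the expression of regulatory T cell genes follows the titles. FOXP3 (ENSG00000049768), the lineage transcription factor of regulatory T cells, measured 1112 and 1180 CPM in Treg replicates 1 and 2, against 96.1 and 0.34 CPM in Teff replicates 1 and 2. IKZF2 (ENSG00000030419), which encodes the transcription factor Helios, measured 172 and 311 CPM in the Treg libraries and 53.5 and 15.6 CPM in the Teff libraries. CTLA4 (ENSG00000163599), an inhibitory receptor, measured 515 and 1794 CPM against 429 and 747 CPM, so that Teff replicate 2 lay above Treg replicate 1. IL2RA (ENSG00000134460), the gene of the sort marker CD25, measured 809 and 786 CPM against 59.5 and 72.9 CPM. CD27 (ENSG00000139193) measured 216 and 234 CPM against 140 and 0.45 CPM. IL2RA and CD27 encode sort markers and are no finding. The fitted log2 fold of Treg over Teff libraries was 4.57 ± 1.60 (SE, n = 2 per group) for FOXP3, 2.80 ± 0.78 for IKZF2 and 0.97 ± 0.72 for CTLA4, with edgeR quasi-likelihood adjusted p of 0.436, 0.407 and 0.887. The CTLA4 log2 fold was -0.19 without Treg replicate 2, and the IKZF2 log2 fold was 3.98 without Teff replicate 1 and 2.17 without Teff replicate 2. The FOXP3 log2 fold was 11.72 without Teff replicate 1 and 3.57 without Teff replicate 2, and its adjusted p was 0.00701 without Treg replicate 1 and 0.00772 without Treg replicate 2. Over all alternatives the adjusted p ranged from 1.07e-06 (DESeq2 with the tumour as a block) to 0.98 for FOXP3 and from 0.0302 to 0.98 for IKZF2. The labels' sort strategy gives the gate CD25+CD27+ to both libraries of tumour 1 and CD25-CD27- to both libraries of tumour 2, which goes against the titles. FOXP3, IKZF2 and IL2RA were higher in each library titled Treg than in each titled Teff, and the groups below follow the titles.

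**Figure D1:**
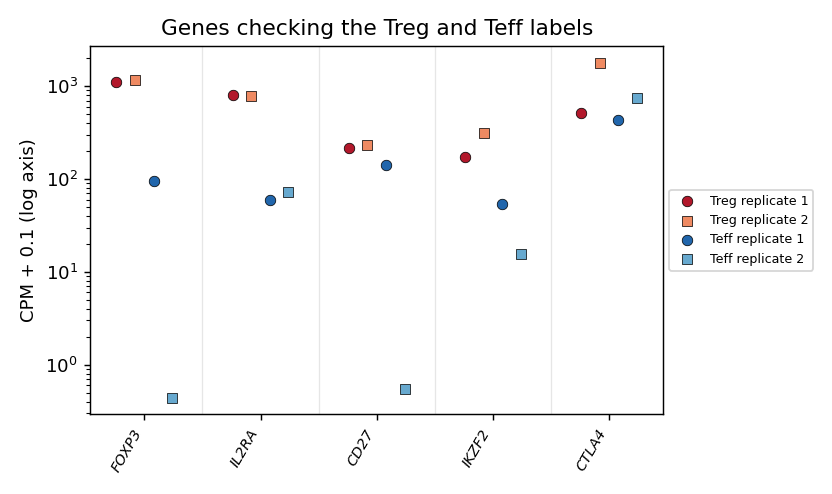
CPM plus 0.1 on a log axis for 5 genes in each of the 4 libraries; every point is 1 library, circles are tumour 1 and squares tumour 2. FOXP3 lies at 1112 and 1180 CPM in the Treg libraries and at 96.1 and 0.34 CPM in the Teff libraries, while CTLA4 overlaps between the groups.

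The second comparison asked which genes differ between regulatory and effector CD4 T cells of the same melanoma lesions, as labelled. The genes of the interleukin-1 receptors had among the smallest p-values of those higher in the Treg libraries. IL1R2 (ENSG00000115590), a decoy receptor that binds interleukin-1 without signalling, measured 204 and 128 CPM in the Treg libraries and 0.73 and 0.23 CPM in the Teff libraries, a log2 fold of 8.37 ± 0.97 (SE, n = 2 per group, adjusted p = 0.109). IL1R1 (ENSG00000115594), the signalling receptor, measured 170 and 275 CPM against 1.51 and 0.45 CPM, a log2 fold of 7.78 ± 0.93 (adjusted p = 0.119). CD40LG (ENSG00000102245), the ligand through which helper T cells activate B cells and dendritic cells, measured 0.18 and 0.05 CPM in the Treg libraries and 260 and 54.1 CPM in the Teff libraries, a log2 fold of -10.20 ± 1.27 (adjusted p = 0.109). ALOX5AP (ENSG00000132965), which encodes the protein that presents arachidonic acid to 5-lipoxygenase in leukotriene synthesis, measured 10.5 and 8.91 CPM against 276 and 230 CPM, a log2 fold of -4.70 ± 0.68 (adjusted p = 0.32). None of these genes passed an adjusted p of 0.05 in edgeR's quasi-likelihood test. With the tumour as a block, a pairing that a check on donor-linked genes left uncertain for 1 of the 2 tumours, the adjusted p was 0.00198 for IL1R2, 0.00243 for IL1R1, 0.00136 for CD40LG and 0.0284 for ALOX5AP. With 1 library left out, log2 folds ranged from 7.81 to 9.50 for IL1R2, from 7.19 to 8.94 for IL1R1, from -11.38 (without Treg replicate 1) to -8.62 (without Teff replicate 1) for CD40LG and from -4.83 to -4.54 for ALOX5AP. Over all alternatives the adjusted p ranged from 3.81e-17 (DESeq2) to 0.98 for IL1R2, from 5.5e-15 to 0.98 for IL1R1, from 1.99e-16 to 0.825 for CD40LG and from 4.66e-09 to 0.98 for ALOX5AP.

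The remaining genes among the 8 with the smallest p in each direction did not pass edgeR's quasi-likelihood test either. DESeq2's Wald test called all those named in this paragraph, with adjusted p from 4.57e-12 for ANK3 to 0.000391 for LAPTM4B, and limma-voom called none of them. On the higher side, FANK1 (ENSG00000203780) measured 73.1 and 22.5 CPM in the Treg libraries against 0.32 and 0.17 CPM, and METTL7A (ENSG00000185432) 98.1 and 43.3 CPM against 2.24 and 2.16 CPM. ZBTB32 (ENSG00000011590), a zinc finger transcriptional repressor, measured 71.8 and 104 CPM against 6.08 and 4.60 CPM. PARD6G (ENSG00000178184), a cell polarity gene, measured 133 and 44.5 CPM against 4.99 and 2.27 CPM, and LAPTM4B (ENSG00000104341), a lysosomal membrane protein gene, 93.9 and 162 CPM against 11.4 and 11.9 CPM. On the lower side, ANK3 (ENSG00000151150), which encodes an ankyrin that anchors membrane proteins to the cytoskeleton, measured 0.85 and 0.32 CPM in the Treg libraries against 73.5 and 69.5 CPM. CYB561 (ENSG00000008283) measured 0.07 and 0.32 CPM against 49.3 and 32.7 CPM, and LRATD2 (ENSG00000168672) 0.59 and 0.32 CPM against 24.5 and 80.1 CPM. MTSS1 (ENSG00000170873), an actin regulator, measured 0.59 and 0.11 CPM against 30.4 and 60.1 CPM. STX3 (ENSG00000166900), a syntaxin of membrane fusion, measured 0.11 and 0.16 CPM against 11.3 and 106 CPM, and ENPP4 (ENSG00000001561) 0.07 and 0 CPM against 31.8 and 67.5 CPM. The blocked adjusted p was 0.0304 for ANK3, 0.0396 for STX3 and 0.0304 for ENPP4. For the other genes of this paragraph it ranged from 0.0705 for FANK1 to 0.353 for LAPTM4B, so they did not pass.

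**Figure D2:**
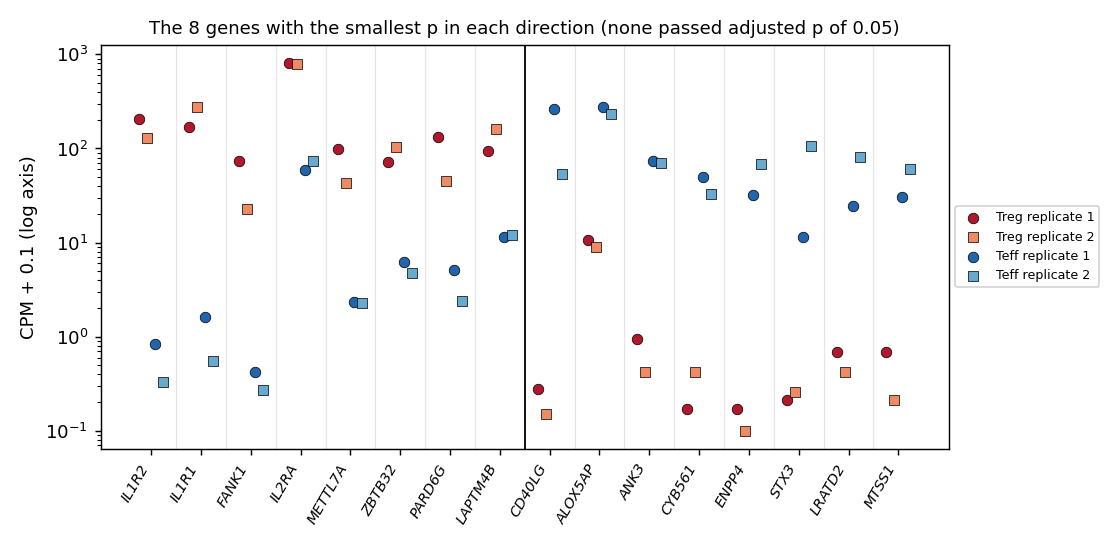
CPM plus 0.1 on a log axis for the 8 genes with the smallest p in each direction, higher in Treg libraries on the left and lower on the right; every point is 1 library, circles are tumour 1 and squares tumour 2. None of these genes passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, while DESeq2's Wald test called all 16; IL1R2 lies at 204 and 128 CPM in the Treg libraries and CD40LG at 260 and 54.1 CPM in the Teff libraries.

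Over all 17481 tested genes, edgeR's quasi-likelihood test called 0 at an adjusted p of 0.05. At an unadjusted p under 0.05 it listed 1349 genes, 312 higher and 1037 lower in the Treg libraries. DESeq2's Wald test called 66 higher and 282 lower, and limma-voom called 0. DESeq2's lower calls include MLPH, a melanocyte gene, at 76.8 CPM in Teff replicate 2 and 0.18 to 0.63 CPM in the other libraries. Some of the lower calls may therefore not be T cell expression, and how many was not counted. With the tumour as a block edgeR called 2 genes higher, IL1R2 and IL1R1, and 16 lower, among them CD40LG, ALOX5AP and TCF7. Both Treg libraries lay above both Teff libraries for 2742 genes (15.7%) and below them for 3456 (19.8%), where chance gives 16.67% in each direction. Without Treg replicate 1 edgeR called 9 genes higher and 68 lower, and without Treg replicate 2 it called 10 and 60. In simulated counts with the spread of these libraries, the same test called 0% of genes changed 4-fold and 24.3% of genes changed 16-fold. The median log2 fold of all genes was -0.06 here, 0.15 with library size only and -0.23 with upper quartile scaling. Single folds moved by other amounts: the FOXP3 log2 fold was 4.60 and 4.55 in these 2 settings against 4.57, and that of STX3 -8.35 and -9.04 against -8.74.

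The third comparison asked which T cell gene lists differed between the groups. The Treg core list rose: all 13 genes were higher in the Treg libraries, with a median log2 fold of 2.47 (camera adjusted p = 1.55e-08). That list gave an adjusted p = 0.501 with an estimated correlation. In edgeR's quasi-likelihood test, which the gene counts of all lists use unless another test is named, 0 of its genes passed over all genes, 10 had an unadjusted p under 0.05 and 10 passed adjusted over the list alone. DESeq2's Wald test called 2 over all genes (IL2RA and RTKN2) and DESeq2 with the tumour as a block 8. For 11 genes both Treg libraries lay above both Teff libraries. RTKN2 measured 400 and 411 CPM in the Treg libraries against 87.0 and 51.5 CPM (log2 fold 2.55 ± 0.61), and LRRC32, which encodes the docking receptor GARP for latent TGF-beta, 28.0 and 55.2 CPM against 4.12 and 0 CPM. The list holds IL2RA, a sort marker. The tumour Treg list, of genes known from regulatory T cells in tumours, rose too, with 13 of 14 genes higher and a median log2 fold of 2.25 (camera adjusted p = 1.61e-07). That list gave an adjusted p = 0.501 with an estimated correlation, and in edgeR's test 0 of its genes passed over all genes, 9 had an unadjusted p under 0.05 and 7 passed adjusted over the list alone. DESeq2 called 2 over all genes (IL1R2 and LAYN), DESeq2 with the block 5, and edgeR with the block 1 (IL1R2). Besides IL1R2, LAYN, which encodes the hyaluronan receptor layilin, measured 169 and 152 CPM against 22.8 and 18.2 CPM (log2 fold 2.97 ± 0.65). BATF, a transcription factor of activated T cells, measured 650 and 331 CPM against 151 and 66.98 CPM, and TNFRSF9, the costimulatory receptor 4-1BB, 127 and 296 CPM against 41.9 and 60.6 CPM.

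The MHC class II list, antigen presentation genes that activated human T cells also express, rose with all 8 genes higher and a median log2 fold of 1.501 (camera adjusted p = 1.22e-04). It gave an adjusted p = 0.501 with an estimated correlation, and in edgeR's test 0 genes passed over all genes, 3 had an unadjusted p under 0.05 and 1 passed adjusted over the list alone. DESeq2 called HLA-DMA over all genes (adjusted p = 0.0248). HLA-DMA, whose product helps to load peptides onto class II molecules, measured 322 and 195 CPM in the Treg libraries against 56.1 and 35.2 CPM (log2 fold 2.50 ± 0.65). HLA-DPB1 measured 415 and 265 CPM against 85.3 and 105 CPM, and CD74, the invariant chain, 3478 and 2296 CPM against 1057 and 1230 CPM. The CD3+ CD4+ gate excludes B cells and myeloid cells, which also express class II genes. Markers of B and plasma cells summed to 173 and 169 CPM in the Treg libraries against 74.6 and 31.9 CPM, and myeloid markers went the other way, at 35.7 and 25.8 CPM against 68.8 and 77.8 CPM.

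The naive and central memory list fell, with 10 of 11 genes lower in the Treg libraries and a median log2 fold of -2.12 (camera adjusted p = 6.69e-04). It gave an adjusted p = 0.692 with an estimated correlation, and in edgeR's test 0 genes passed over all genes, 5 had an unadjusted p under 0.05 and 5 passed adjusted over the list alone. DESeq2 called 4 over all genes (NELL2, TCF7, BACH2 and KLF2), DESeq2 with the block 5, and edgeR with the block 1 (TCF7). TCF7, a transcription factor of naive and memory T cells, measured 34.1 and 6.17 CPM against 500 and 181 CPM (log2 fold -4.07 ± 0.96, adjusted p = 0.407, blocked adjusted p = 0.0357). IL7R, the receptor for the survival cytokine interleukin-7, measured 106 and 99.4 CPM against 549 and 346 CPM (log2 fold -2.12 ± 0.59). KLF2, a regulator of T cell migration, measured 15.6 and 4.33 CPM against 118 and 67.04 CPM, and NELL2 16.2 and 6.17 CPM against 174 and 187 CPM. Without Teff replicate 1 the list gave an adjusted p of 0.233.

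The immediate early and heat shock list fell, with all 14 genes lower in the Treg libraries and a median log2 fold of -1.55 (camera adjusted p = 0.00106). It gave an adjusted p = 0.692 with an estimated correlation, and in edgeR's test 0 genes passed over all genes or adjusted over the list alone, and 2 had an unadjusted p under 0.05. DESeq2 called 0 over all genes, and DESeq2 with the block 5. Treg replicate 1 was the lowest of the 4 libraries for all 14 genes. FOS, a transcription factor gene induced within minutes of stimulation, measured 7.29 CPM in Treg replicate 1, 1840 CPM in Treg replicate 2, 4748 CPM in Teff replicate 1 and 989 CPM in Teff replicate 2. DNAJB1, a co-chaperone, measured 260 and 2407 CPM in the Treg libraries and 2921 and 8780 CPM in the Teff libraries. HSPA1A, at 57.3 and 298 CPM against 432 and 4453 CPM, and HSPA1B are near-identical copies, so the split of reads between them is uncertain. Median log2 ratios of Treg to Teff were -3.49 in tumour 1 and -0.21 in tumour 2. In tumour 2 the heat shock genes HSPA1A, HSPA1B, DNAJB1, HSPH1 and HSPB1 had log2 ratios from -3.90 to -1.01, and the immediate early genes from -0.92 for DUSP1 to 1.58 for IER2. The list gave an adjusted p of 0.674 without Treg replicate 1 and of 0.112 without Teff replicate 1.

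**Figure D3:**
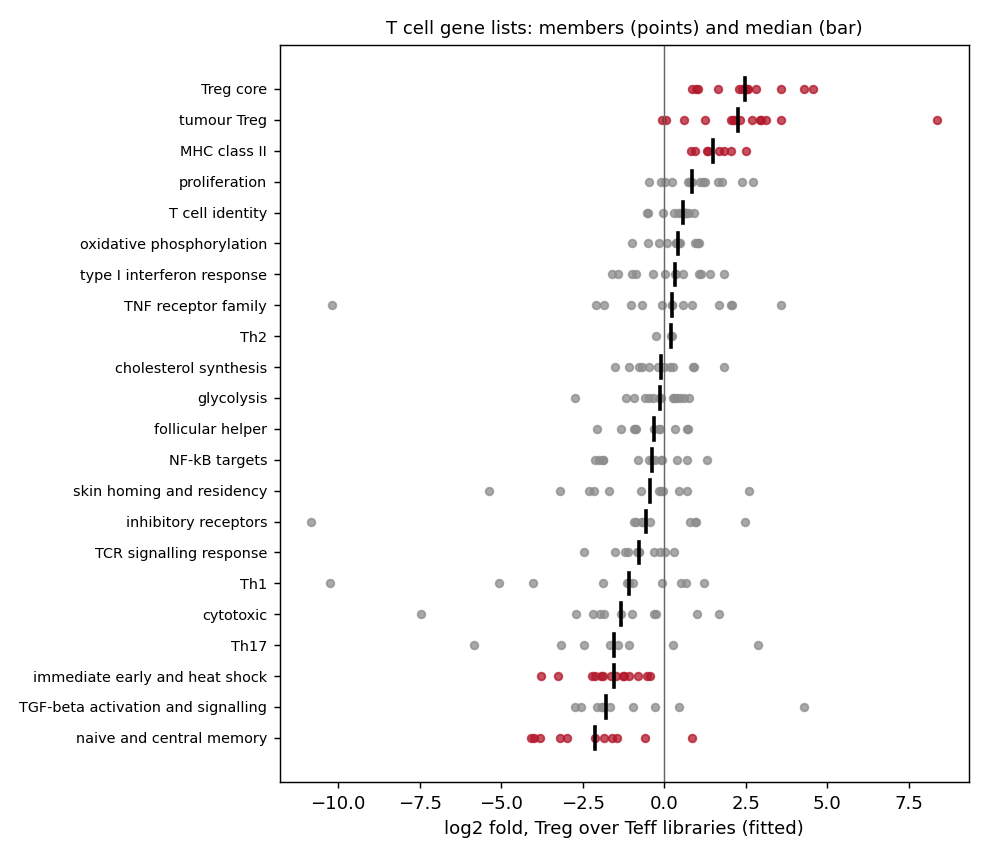
Fitted log2 fold of Treg over Teff libraries for the tested genes of 22 T cell gene lists, fitted with 2 libraries per group; points are genes, bars are list medians, and red lists passed camera with the preset correlation. The Treg core median lies at 2.47 and the naive and central memory median at -2.12.

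Helper programme lists did not pass camera with the design and filter fixed for the comparison. Genes without a filled row, such as CCL5 of the Th1 list and CCL3 and CCL4 of the cytotoxic list, did not enter these tests. In the Th1 list 8 of 11 genes were lower in the Treg libraries, with a median log2 fold of -1.10 (adjusted p = 0.0614, but 0.0159 with the tumour as a block, 0.0295 with the stricter filter and 1.87e-05 without Treg replicate 2). IL2, the T cell growth factor gene, was at 0 in both Treg libraries and at 6.59 and 7.73 CPM in the Teff libraries, and CSF2, which encodes GM-CSF, at 0 and 2.74 CPM against 32.4 and 53.0 CPM. EOMES measured 6.45 and 0 CPM against 25.3 and 84.7 CPM. In the Th17 list 6 of 8 genes were lower, with a median of -1.54 (adjusted p = 0.111, but 0.022 with the stricter filter and 0.0362 without Treg replicate 2). KLRB1, the gene of CD161, measured 7.96 and 5.64 CPM against 74.9 and 48.7 CPM, while RORA measured 1521 CPM in Teff replicate 2 and 124 to 228 CPM in the other libraries. The Th2 list had 3 tested genes with a median of 0.19 (adjusted p = 0.833), of which GATA3 measured 202 and 191 CPM against 217 and 119 CPM. In the follicular helper list 8 of 11 genes were lower, with a median of -0.32 (adjusted p = 0.585), and CD200 measured 20.8 and 42.1 CPM against 145 and 117 CPM. In the cytotoxic list 9 of 11 genes were lower, with a median of -1.33 (adjusted p = 0.195). GNLY, which encodes the cytolytic protein granulysin, measured 4932 CPM in Teff replicate 2 and 2.16 to 25.8 CPM in the other libraries. In edgeR's test none of the genes in these 5 lists passed over all genes, while DESeq2 called IL2 (adjusted p = 0.000315), KLRB1 (0.00341) and GNLY (0.00288). Adjusted over the list alone, 2 genes of the Th17 list passed edgeR's test and 0 of the other lists.

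Receptor and signalling lists did not pass camera with that design and filter either, and 3 of them passed it in other settings. The TNF receptor family list, with its ligands, had 8 of 14 genes higher and 6 lower. Its median log2 fold was 0.23 and its mean -0.34, and camera placed it upward (adjusted p = 0.607). TNFRSF1B, the gene of TNF receptor 2, measured 1894 and 2492 CPM in the Treg libraries against 529 and 521 CPM (log2 fold 2.06 ± 0.60), while TNFRSF10B, a TRAIL receptor gene, measured 40.0 and 35.2 CPM against 104 and 169 CPM. CD40LG was the 1 gene of this list that passed adjusted over the list alone. The inhibitory receptor list had a median of -0.56 and a mean of -0.93, while camera placed it upward (adjusted p = 0.918). TIGIT measured 1805 and 900 CPM against 407 and 80.2 CPM, and CD244 was at 0 in both Treg libraries and at 18.9 and 2.22 CPM in the Teff libraries. In the skin homing and residency list, with a median of -0.43 (adjusted p = 0.257, but 0.00434 without Treg replicate 2), ITGA1, the gene of the collagen-binding integrin CD49a, measured 0.99 and 0.84 CPM against 48.5 and 28.97 CPM. CXCR6, a chemokine receptor of tissue T cells, went the other way at 1138 and 824 CPM against 240 and 82.8 CPM (log2 fold 2.60 ± 0.70). Of that list 2 genes passed adjusted over the list alone. The TGF-beta activation and signalling list had 8 of 10 genes lower and a median of -1.78 (adjusted p = 0.111, but 0.0104 with the stricter filter and 0.0287 without Treg replicate 2). SMAD7, a feedback inhibitor of TGF-beta signalling, measured 9.39 and 22.8 CPM against 75.8 and 138 CPM, and LRRC32 was higher as given above. The NF-kB target list had a median of -0.37 (adjusted p = 0.514), with NFKBIA, the gene of the NF-kB inhibitor, at 411 and 746 CPM against 817 and 3443 CPM. The TCR signalling response list had a median of -0.78 (camera adjusted p = 0.199, but 0.0207 with the stricter filter). Its median log2 ratio of Treg to Teff was -3.33 in tumour 1 and 0.19 in tumour 2. NR4A2, an early response nuclear receptor gene, measured 39.2 and 644 CPM against 1858 and 1897 CPM. Adjusted over the list alone, 0 genes passed edgeR's test in the inhibitory receptor, TGF-beta, NF-kB and TCR lists. DESeq2 called CD40LG, CD244, ITGA1 and CXCR6 of these 6 lists over all genes.

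Growth and metabolism lists did not pass camera. In the proliferation list 13 of 15 genes had folds above 0 and the median was 0.86 (adjusted p = 0.265), with MKI67, a marker of cycling cells, at 42.6 and 130 CPM in the Treg libraries against 29.7 and 46.1 CPM. Its adjusted p was 4.8e-05, upward, without Treg replicate 1 and 0.0145, downward, without Treg replicate 2. The type I interferon list had a median of 0.34 (adjusted p = 0.308, and 0.042 without Teff replicate 1), with OAS1, an antiviral enzyme gene, at 145 and 173 CPM against 81.5 and 7.67 CPM. The oxidative phosphorylation list had 11 of 14 genes higher and a median of 0.42 (adjusted p = 0.116), with SDHA at 348 and 261 CPM against 138 and 156 CPM. The glycolysis list had a median of -0.13 and a mean of -0.27 while camera placed it upward (adjusted p = 0.919). SLC2A3, the gene of the glucose transporter GLUT3, measured 228 and 376 CPM against 1110 and 2888 CPM (log2 fold -2.73 ± 0.72). The cholesterol synthesis list had a median of -0.11 and a mean of -0.05 while camera placed it upward (adjusted p = 0.554), with FDFT1, the gene of squalene synthase, at 216 and 241 CPM against 128 and 117 CPM. The T cell identity list had a median of 0.57 (adjusted p = 0.168). CD3D, a chain of the T cell receptor complex, measured 565 and 502 CPM in the Treg libraries, 570 CPM in Teff replicate 1 and 96.9 CPM in Teff replicate 2. Adjusted over the list alone, 0 genes passed edgeR's test in these 6 lists, and DESeq2 called SLC2A3 over all genes (adjusted p = 0.0486).

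Markers of other cell types were measured beside these groups. Melanocyte and melanoma markers summed to 10.1 and 15.5 CPM in the Treg and Teff libraries of tumour 1, and to 443 and 3836 CPM in those of tumour 2. PMEL, a melanosome gene, measured 2160 CPM in Teff replicate 2, 269 CPM in Treg replicate 2, 3.83 CPM in Treg replicate 1 and 1.60 CPM in Teff replicate 1. TYRP1, a pigment synthesis gene, measured 1322 CPM in Teff replicate 2 and was at 0 in the other libraries. This list had a median log2 fold of -0.81 (camera adjusted p = 0.633, and 0.00184 without Treg replicate 2). KIT, listed as a mast cell marker and also expressed by melanocytes, measured 240 CPM in Teff replicate 2 and was at 0 elsewhere. The B and plasma cell list had a median of 1.75 (adjusted p = 0.514), with CD79A at 53.9 and 5.17 CPM in the Treg libraries against 1.14 and 0.74 CPM, and MS4A1 at 0 and 0.11 CPM against 8.92 and 18.6 CPM. The myeloid list had a median of -0.67 (adjusted p = 0.173), with MS4A6A at 1.44 and 1.42 CPM against 49.4 and 15.3 CPM. The keratinocyte list had a median of 0.77 (adjusted p = 0.351), with KRT14 at 2.54 and 13.3 CPM against 0.09 and 0.11 CPM. The fibroblast list had 3 tested genes and a median of -1.15 (adjusted p = 0.111, but 0.0452 with the tumour as a block and 0.00348 without Treg replicate 2), with COL1A1 at 0.52 and 0.16 CPM against 6.68 and 32.95 CPM. The red blood cell list had a median of 0.69 (adjusted p = 0.175, but 0.01 without Teff replicate 2), with HBB at 27.5 and 51.1 CPM against 4.99 and 29.3 CPM. Adjusted over the list alone, 2 genes passed in the B and plasma cell list, 1 in the myeloid list, 1 in the fibroblast list and 0 in the other lists of this paragraph with edgeR's test. DESeq2 called 2 over all genes in the B and plasma cell list, 3 in the myeloid list, 1 in the keratinocyte list and 1 in the fibroblast list.

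Lists with fewer than 3 tested genes were not tested. Their sums in Treg replicates 1 and 2 and Teff replicates 1 and 2 were 0.1, 0, 5.3 and 7.7 CPM for CD8 T cell markers, 16, 8.2, 9.9 and 17 CPM for NK cell markers, and 12.2, 15, 6.2 and 10 CPM for dendritic cell markers. They were 0.3, 1, 0 and 241.6 CPM for mast cell markers and 0.7, 0.6, 2.1 and 5.0 CPM for endothelial cell markers. CD8A, the gene of a protein that the sort excluded, measured 0.04 and 0.05 CPM in the Treg libraries against 5.08 and 7.73 CPM.

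**Figure D4:**
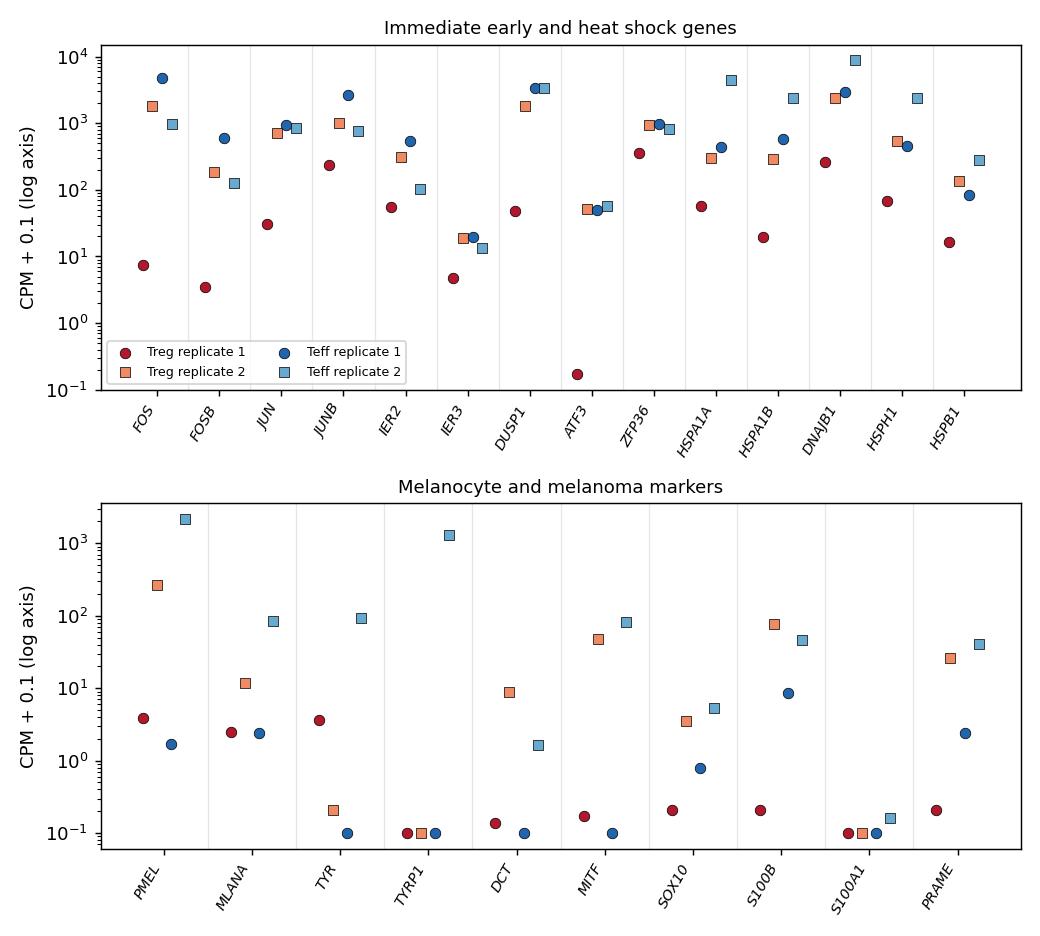
CPM plus 0.1 on a log axis for the immediate early and heat shock genes and for the melanocyte and melanoma markers; every point is 1 library, circles are tumour 1 and squares tumour 2. Treg replicate 1 is the lowest library for all 14 genes of the upper panel, and TYRP1 in the lower panel lies at 1322 CPM in Teff replicate 2 and at 0 in the other libraries.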

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

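The tests on IL2RA, on the TYRP1 share and on immediate early and heat shock genes were chosen only after the result was seen.

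The titles and the sort strategy label give opposite gates to Treg replicate 2 and to Teff replicate 1. If the sort label gave each library's gate, IL2RA would be higher in both libraries of tumour 1. The lowest IL2RA level of the libraries titled Treg was 10.8 times the highest of those titled Teff, which argues against that reading. CD27, the other marker of the gate, was at 216, 234, 140 and 0.45 CPM in Treg replicate 1, Treg replicate 2, Teff replicate 1 and Teff replicate 2, so that its level in Treg replicate 2 goes with the title and that in Teff replicate 1 with the sort label. No biological explanation was tested for this pattern.

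Melanocytic transcripts were abundant in Teff replicate 2, although the gate (CD45+ CD3+ CD4+) excludes melanocytic cells. RNA of melanocytic cells may have reached this library: besides 9 of the 10 listed markers that drew attention to it (PMEL 2160 and TYRP1 1322 CPM), 8 of 10 melanocyte genes outside the list, chosen before their values were seen, were over 4 times their level in tumour 1 and over 1 CPM, with TRPM1 at 109 and MLPH at 76.8 CPM, and in Treg replicate 2 this held for 7 of the listed and 3 of the added genes. A single pool of free RNA in both libraries of tumour 2 is argued against, since TYRP1 made up 38.0% (exact 95% binomial interval 37.6% to 38.4%) of TYRP1 plus PMEL reads in Teff replicate 2 but 0 of 5099 reads (up to 0.072%) in Treg replicate 2. The intervals cover counting error only. Amplified reads are not independent molecules, so loss of TYRP1 RNA before amplification is not covered. The test also takes both libraries to come from tumour 2, as labelled, and the check on donor-linked genes left the pairing uncertain for 1 tumour. Replacement of T cells by other cells with nothing else changed would move the 12 T cell identity genes by 1 common factor. Their log2 ratios to the other libraries had an SD of 1.16 (95% interval 0.83 to 1.98), from -2.48 for CD3D to 0.98 for CD28. An SD over 1 had been set beforehand as going against this replacement, and the value was over it. The interval, which treats the genes as independent, reached below 1, so the value met this rule but the lower bound did not. Under 1 common factor all genes would move the same way, but 10 were lower than in the other libraries and 2 higher (PTPRC 0.66 and CD28 0.98). These values argue against replacement with nothing else changed, for these 12 genes in this library. Replacement of T cells together with other changes was not tested and stays open. A small amount of starting RNA stays open as well, since 0.613% of genes over 20 CPM in the other 3 libraries were under 1 CPM here, against 0.161%, 0.359% and 0% in Treg replicate 1, Treg replicate 2 and Teff replicate 1. These genes include FOXP3 and CD27, which cell type or gate can lower, so the share does not measure RNA input alone. Genes with at least 10 reads numbered 17714 here, against 17436, 14369 and 17439 in the same 3 libraries.

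Immediate early and heat shock genes had a median Treg to Teff log2 ratio of -3.49 in tumour 1 and -0.21 in tumour 2, where heat shock genes stayed below 0 (HSPA1A -3.90, DNAJB1 -1.87) and immediate early genes went both ways (DUSP1 -0.92, FOS 0.90). An equal difference between Treg and Teff cells in both tumours is not excluded, although the median difference between tumours was 3.20 on the log2 scale, 13 of 14 genes had the lower ratio in tumour 1 and 8 of 14 a ratio below 0 in tumour 2, because 1 pair of libraries per tumour gives no spread for it and the genes move together. Handling or digestion that differed between single libraries could also give the pattern, since 14 of 14 genes were lowest in Treg replicate 1, and no label separates handling from lesion or cell type. These explanations cannot be told apart with 1 library per tumour and cell type. The comparison of tumours also rests on the labelled pairing, which the check on donor-linked genes left uncertain for 1 tumour.

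Several lists and genes had opposite Treg to Teff log2 ratios in the 2 tumours, of at least 0.5 in both for a list and 1 for a gene, and these differences were not tested, with 1 pair of libraries per tumour. The pairs follow the labels, and for 1 of the 2 tumours the libraries did not match in donor-linked genes, so they may not share a lesion. The median log2 ratio in tumour 2 minus that in tumour 1 was 3.12 for the proliferation list. The same difference was 2.20 for the type I interferon list. It was 1.72 for the follicular helper list. It was 1.71 for the Th2 list, which has 3 tested genes. It was 1.27 for the inhibitory receptor list. Below that minimum in 1 tumour, but further apart than these, were the TCR signalling response list (median -3.33 in tumour 1 and 0.19 in tumour 2) and the myeloid list (0.40 and -3.14). For single genes, ratios use a prior count of 2 reads, which sets their size where a library is at 0. The difference was -12.20 for GNLY, with 4932 CPM in Teff replicate 2. It reached 7.15 for CCNB2, a cyclin gene, at 3.17 and 52.0 CPM in the Treg libraries and 9.33 and 0.97 CPM in the Teff libraries. Melanosome genes gave -14.12 for TYR, which was at 0 in Teff replicate 1, and -4.22 for PMEL. KRTDAP, a keratinocyte gene, gave -9.33, with 0 reads in Treg replicate 2 and Teff replicate 1.

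Reads in no gene, which enter no comparison, made up 14.1% of the reads listed for Treg replicate 1, 11.1% for Treg replicate 2, 12.2% for Teff replicate 1 and 21.5% for Teff replicate 2.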

How the results depend on the processing

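All alternatives in this part were planned. The count of 0 genes higher and 0 lower in the Treg libraries (edgeR's quasi-likelihood test, 1349 genes at an unadjusted p under 0.05) became 2 and 16 with the replicate block, 2 and 1 with upper quartile scaling, 2 and 1 with the stricter filter, 66 and 282 with DESeq2's Wald test and 117 and 353 with DESeq2 and the block. It stayed at 0 and 0 with DESeq2 size factors, library size only, limma-voom, no filter, without mitochondrial, ribosomal protein and receptor genes, at a threshold of 0.10 and with the legacy fit. The 18 genes called with the block were all among the 470 called by DESeq2 with the block. With 1 library left out, the count higher ranged from 0 to 10 and the count lower from 0 to 68; the lone library left in an arm is then assumed to vary like the other group, and the cause of the larger counts was not tested. Of the 5 lists called by camera, 0 were called with an estimated correlation and 0 by fry's directional test, while the stricter filter, which tested 22 lists, called 9 and kept the 5. The 4 it added were TCR signalling response, TGF-beta activation and signalling, Th1 and Th17. With 1 library left out, 4 to 13 lists were called, 13 of them without Treg replicate 2, where those 4, skin homing and residency, proliferation, fibroblast and melanocyte lists were added. DESeq2 size factors and a prior count of 0.5 kept all 5, and the block kept them and added the Th1 and fibroblast lists. Fry's mixed test, which has no direction, called 5 lists and kept 1 of camera's, MHC class II (9.32e-05), beside Th1 (0.0344), TNF receptor family (0.0344), skin homing and residency (0.0374) and Th17 (0.0374). The proliferation list turned downward without Treg replicate 2 (adjusted p = 0.0145), and its adjusted p ranged from 4.79e-05 to 0.565 over the libraries left out. CTLA4 had a log2 fold of -0.19 without Treg replicate 2, and its fold ranged up to 1.61 without Treg replicate 1. The TNF receptor family list was the other of the 2 list results counted as turned, in fry's mixed test, since fry's direction there is that of its directional test and camera placed the list upward. A change of sign was not counted for lists called in neither setting. With the block DESeq2 called 470 genes against 348 without it, and 270 were shared. Within lists, DESeq2's calls over all genes rose with the block from 1 to 4 for Th1 and from 1 to 3 for the TNF receptor family. They rose from 0 to 2 for TGF-beta activation and signalling, and further lists changed too. Each tumour alone gave ratios per gene and no count. Depth was 18638373 assigned reads or more per library, and in simulated counts with the spread of these libraries 24.3% of 16-fold changes were called and 0% of 4-fold changes.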

Other observations

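The genes of this part were chosen after their values were seen, lie outside the fixed lists unless stated, and did not pass edgeR's quasi-likelihood test over all genes. DESeq2's Wald test called PTGER2, PTGDR, CYSLTR2, ANXA1, NFIL3, CHD7, HSPA6 and THEMIS, with adjusted p from 1.14e-06 for CYSLTR2 to 0.0104 for THEMIS. The other genes of this part were not among its calls. PTGER2, a prostaglandin E2 receptor gene, measured 1.55 and 0 CPM in the Treg libraries against 72.9 and 44.7 CPM in the Teff libraries. PTGER4, another such receptor gene and part of the skin homing list, measured 31.3 and 169 CPM against 543 and 349 CPM. PTGDR, a prostaglandin D2 receptor gene, was at 0 in both Treg libraries and at 13.2 and 9.09 CPM in the Teff libraries. CYSLTR2, a cysteinyl leukotriene receptor gene, was at 0 against 11.9 and 26.4 CPM. CYSLTR1 measured 14.9 and 22.7 CPM against 97.1 and 31.3 CPM, and LTB4R 5.12 and 1.74 CPM against 17.7 and 16.6 CPM. PTGIR, the prostacyclin receptor gene, measured 19.5 and 0.37 CPM against 1.51 and 4.54 CPM. IL1RAP, which encodes the coreceptor of interleukin-1 receptors, measured 26.1 and 78.0 CPM in the Treg libraries against 21.0 and 25.7 CPM.

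Among genes lower in the Treg libraries that passed with the tumour as a block, ANXA1, an anti-inflammatory phospholipid-binding protein gene, measured 4.09 and 77.8 CPM against 804 and 1792 CPM (blocked adjusted p = 0.0154). NFIL3, a basic leucine zipper transcription factor gene, measured 0.74 and 2.90 CPM against 29.4 and 412 CPM (0.0154). CHD7, a chromatin remodeller gene, measured 2.03 and 12.9 CPM against 99.6 and 435 CPM (0.0154). HSPA6, a stress-inducible heat shock gene, measured 4.13 and 9.65 CPM against 87.4 and 2781 CPM (0.0213). Outside these calls, THEMIS, a regulator of T cell receptor signalling, measured 34.8 and 40.1 CPM in the Treg libraries against 191 and 303 CPM. DPP4, the gene of CD26, measured 13.7 and 0.16 CPM against 135 and 66.4 CPM. F5, the coagulation factor V gene, was higher in the Treg libraries, at 334 and 346 CPM against 62.7 and 7.73 CPM.

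Correlations of log2 CPM across genes, which are not independent replicates, were 0.804 to 0.85 among the other 3 libraries and 0.708 to 0.784 between Teff replicate 2 and each of them. Splitting the 4 libraries by title gave 1349 genes at an unadjusted p under 0.05, against 871 by tumour, which is also the split of the sort label, and 888 by the crossed split. EdgeR called 0 genes at an adjusted p of 0.05 in each of these splits, and 3 splits are too few for a share under 0.05.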
